A study of Mus musculus with 18 samples.

How the data were processed

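Genomic DNA from the tails of 9 C57BL/6 mice, a sire, a dam and 7 progeny of 1 family, was hybridised on 2-colour oligonucleotide arrays against DNA of 1 reference male from the same colony, per the labels and the series' design text. Each animal was hybridised on 2 arrays with the dyes exchanged, so there were 18 arrays. Groups and dye orientation were taken from the channel labels. The labels number the reference mouse differently in sample titles and source names, and it was treated as 1 animal. Per the file headers the arrays were read on 5 slides, with the sire and dam on slide 1, progeny 1 and 2 on slide 2, progeny 3 and 4 on slide 3, progeny 5 and 6 on slide 4 and progeny 7 on slide 5. There were 3 scan days: slides 1 and 2, slides 3 and 4, and slide 5.

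Per the file headers, the authors' scanner files were made with Agilent Feature Extraction 12.1.0.3 with probe positions on mm9 (NCBI37). The deposited processed signals are intensities on a linear scale that were background-subtracted, spatially detrended and dye-normalized by a linear factor, per the file headers. The files also hold raw median intensities of each spot and its local background, as deposited. The deposited LogRatio column is log10 of Cy5 over Cy3. It differed from the ratio of processed signals by a median of 0.00, and by at most 0.32 at any spot on a log2 scale. The series' deposited value table holds log2 ratios of the same arrays, with the direction, centring and further correction not given in the sources used here. Set against the scanner files, its sign runs as reference over animal on every array (correlation of the turned values 0.975 to 1.00), its column medians lie between -0.002 and 0.011, and on 16 of the 18 arrays it was corrected in some further way whose kind stays unknown. It was used as an alternative only.

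Ratios were computed as log2 of the processed Cy5 over Cy3 intensity, turned so that each is animal over reference, and centred on the median of each array, with no loess or quantile step. Of 143391 spots that were not controls, 0.084% to 0.165% per array carried an outlier flag and were left out. At most 5 spots per array were saturated, and these were kept. Spots of the same probe were averaged, and the 1000 or so probes with at least 4 spots had a median SD between spots of 0.043 to 0.052. The authors' derivative log ratio spread was 0.098 to 0.114 per array. Across all probes, the 2 arrays of an animal correlated at -0.56 to -0.19 once turned, and arrays of different animals in the same orientation at 0.38 to 0.76. A dye bias of each probe therefore dominates a single array, and it cancels in the average of both orientations. The number of arrays limits the precision.

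A probe was counted when its log2 ratio was at least 0.5 from 0 with the same sign on both arrays of an animal. Segments were found on the average of both orientations by optimal partitioning, a penalised least-squares method. A change point cost 3 times the noise variance times the natural log of the number of probes on the chromosome, and breaks were forced at gaps over 100 kb. A segment was called with at least 5 probes, a mean at least 0.25 from 0, and a mean of the same sign at least 0.125 from 0 on each array. The same counts with the sign of 1 array left unturned served as background. Overlapping called segments of the animals were merged into regions, and each animal was called in each region by the rule on means. The regions were then placed in 4 classes: called in all 9 animals, in parent and progeny, in progeny only, or in parents only. Adjoining regions on chromosome 4 are described as 1 interval.

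Progeny were compared with the reference (n = 7, intercept against 0) and with the parents (7 against 2) at every probe by limma 3.58.1 in R 4.3.3, with an adjusted p below 0.05 after Benjamini-Hochberg and a log2 ratio at least 0.25 from 0. In each region, progeny and parents were compared by an exact permutation test of the difference of means, two-sided, over the 36 choices of 2 animals among 9, with Benjamini-Hochberg adjustment. Segmentation and other steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0.

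Tested on simulated data over the 139295 probe positions with noise of 0.05, the segmentation recovered 93 of 100 segments of 5 probes at a log2 size of 0.3, and 100 of 100 at 0.5, with 0 false calls in both. The simulated noise was independent between probes, so the 0 false calls do not cover variation that neighbouring probes share. With the spread of the real probes, limma recovered 98.5% of 200 probes changed by 0.4 in progeny against reference, over 139043 probes, with 1 false call. In progeny against parents it recovered 87.0% at a change of 0.4, with 7 false calls, and 98.5% at a change of 1, with 3. The simulated change was added alike to all 7 progeny, so recovery of a change carried by only some of them was not simulated.

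Tests, thresholds, alternatives and the rule for naming regions were set before the data were examined, except where the text says otherwise. The rule named every region if there were at most 20 in all, and otherwise the 8 with the largest absolute mean in each class (6 in the class of all 9 animals). The short regions, the 2 intervals and the probes that differ between dam and sire were picked out after their values were seen. Alternatives were normexp background correction, the authors' value table, loess, filters on dim and flagged spots, other calling minimums, penalties, breaks and merging, each dye orientation alone, and leaving out animals. Slide as a random block and scan day as a fixed block were tried as well. The planned normexp alternative used median in place of mean signals with an offset of 50. A trend on GC content and the tests of gene lists fixed beforehand need sequence or annotation on mm9, which was not used here, so they were not run. For the same reason no gene is named: the gene table used here is on GRCm38, and positions were not moved between builds.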

Results

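Copy number across the genome was compared by array comparative genomic hybridisation, in which DNA of an animal and DNA of a reference are labelled with different dyes and hybridised to the same probes. The DNA came from the tails of 1 C57BL/6 mouse family: a sire, a dam and 7 progeny. Each of these 9 animals was hybridised against the same reference male on 2 arrays with the dyes exchanged, which gave 18 arrays. Both arrays of an animal hold the same pair of DNAs, so they were averaged and counted as 1 replicate: the sire and the dam have n = 1 each and the progeny n = 7. The series concerns copy number changes in offspring of males kept under gamma rays at 0.05 mGy per day for 400 days. Its title speaks of exposed males, whereas its design text calls the male of this family not irradiated. The channel labels of all 9 animals, the dam and the progeny included, begin with 0.05mGy, which does not settle the point. The exposure of this sire is therefore left open here. No unexposed family is part of the comparisons, and no effect of radiation was tested.

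The array was a second, dense design. Its probes were placed around positions that had stood out in an earlier genome-wide screen of the families, so the probes are not an even sample of the genome and the regions below are not independent of that screen. It carried 139295 distinct probes, 139244 of them on the 19 autosomes, 48 on X and 3 on Y, with a median spacing of 102 bp between neighbours inside a tiled stretch. On every array at least 99.8% of the spots were well above background in both channels. The standard deviation of a probe in the average of the 2 dye orientations, taken from neighbouring probes, lay between 0.041 and 0.056 on the log2 scale over the 9 animals. A mean over 5 probes then has a standard error of 0.018 to 0.025 if neighbouring probes vary independently. The standard deviation over all autosomal probes of an animal was larger, from 0.065 in progeny 4 to 0.097 in the dam. All ratios below are animal over reference, and all positions are on mouse build mm9.

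The sex chromosomes showed the size of a known difference. Against the male reference, the median log2 ratio of the X probes was 0.93 in the dam (SD over 48 probes 0.095) and 0.01 in the sire (SD over 48 probes 0.037). Among the progeny it was 0.95 in progeny 7, and it lay between -0.01 and 0.01 in the other 6. The 3 Y probes had a median of -3.15 in the dam, -4.12 in progeny 7 and 0.03 in the sire. They disagreed widely, from -5.60 to -0.47 in the dam and from -6.03 to -0.55 in progeny 7. Without probes not well above background 1 Y probe was left in each of these 2 animals, at -0.47 and -0.55, so the size of the Y ratio is not fixed by these medians. Progeny 7 thus had the X and Y ratios of a female against a male reference, as the dam did. The other 6 had those of a male, as the sire did. The sex of the progeny is not given in the labels, so progeny were not grouped by these values.

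**Figure D1:**
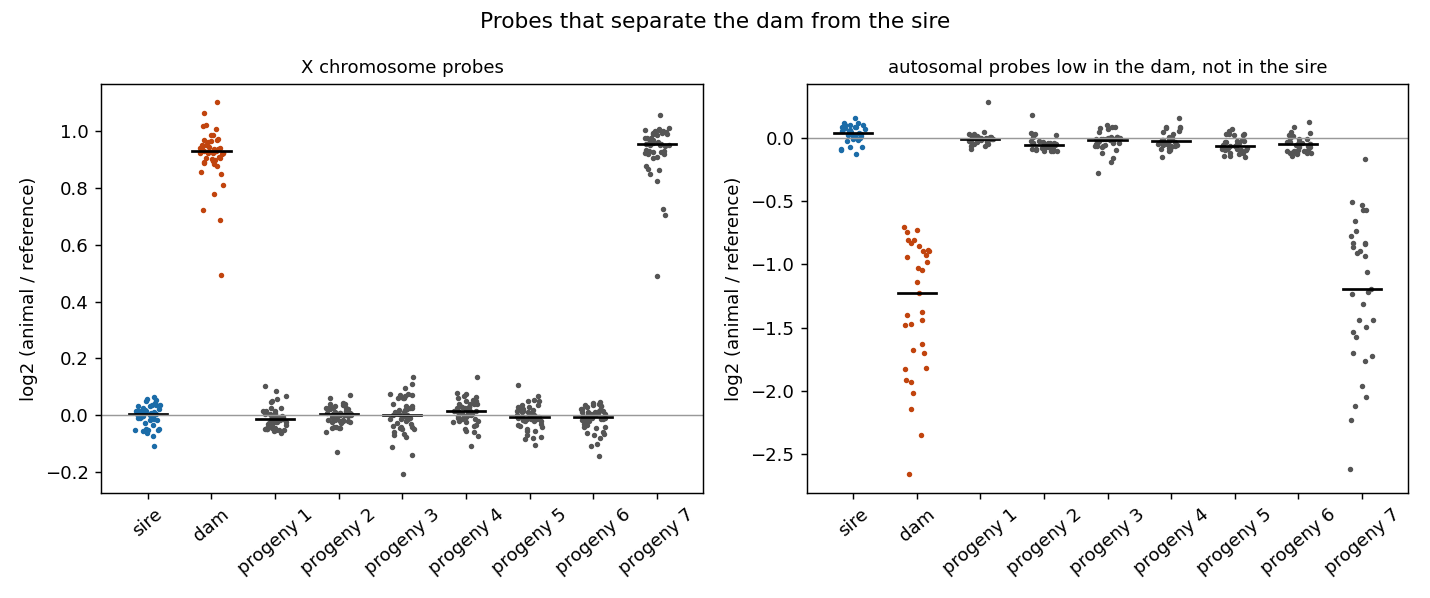
Log2 ratios (animal over reference, vertical axis) of the 48 X probes (left) and of 33 autosomal probes that were low in the dam and not in the sire (right), for each of the 9 animals (horizontal axis). Each point is a probe averaged over both dye orientations and the black bar is the median; X medians are 0.93 in the dam and 0.95 in progeny 7, and the autosomal probes have medians of -1.23 and -1.20 in these animals.

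On the autosomes, animals of the family differed in a higher copy ratio over 159 kb of chromosome 4, from 101112341 to 101270967. Over its 607 probes the mean log2 ratio was 0.52 in the sire and -0.01 in the dam. It was 0.51 in progeny 2, 0.55 in progeny 3, 0.50 in progeny 5, 0.51 in progeny 6 and 0.53 in progeny 7. Progeny 1 and progeny 4 were at -0.01 and 0.00. The sire and 5 of the 7 progeny thus passed the calling rule, and the dam and the other 2 progeny did not.

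Both dye orientations gave this result. In the sire the mean was 0.54 with its DNA in Cy5 and 0.50 with its DNA in Cy3, and in progeny 3 these values were 0.58 and 0.52. The ratio 0.52 in the sire is a 1.44-fold signal, against 1.5-fold for 3 copies over 2. The interval was called as 5 adjoining regions of 245, 256, 31, 25 and 46 probes, with 4 probes of the interval between regions. The next probe on the right ends at 101271028, and the 20 probes beyond that side had means between -0.01 and 0.03 in all 9 animals. On the left the nearest probe ends at 100957081, which leaves 155 kb without a probe, so the left end is placed no better than that. The 5 regions did not pass the test between progeny and parents as groups. Progeny means were 0.11 to 0.13 above the parents' mean, but animals differed widely within both groups. In the first region progeny were at 0.37 ± 0.26 (SD, n = 7) and the parents at 0.26 on average (exact permutation test over 36 choices, two-sided, p = 0.806, adjusted p = 0.936).

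**Figure D2:**
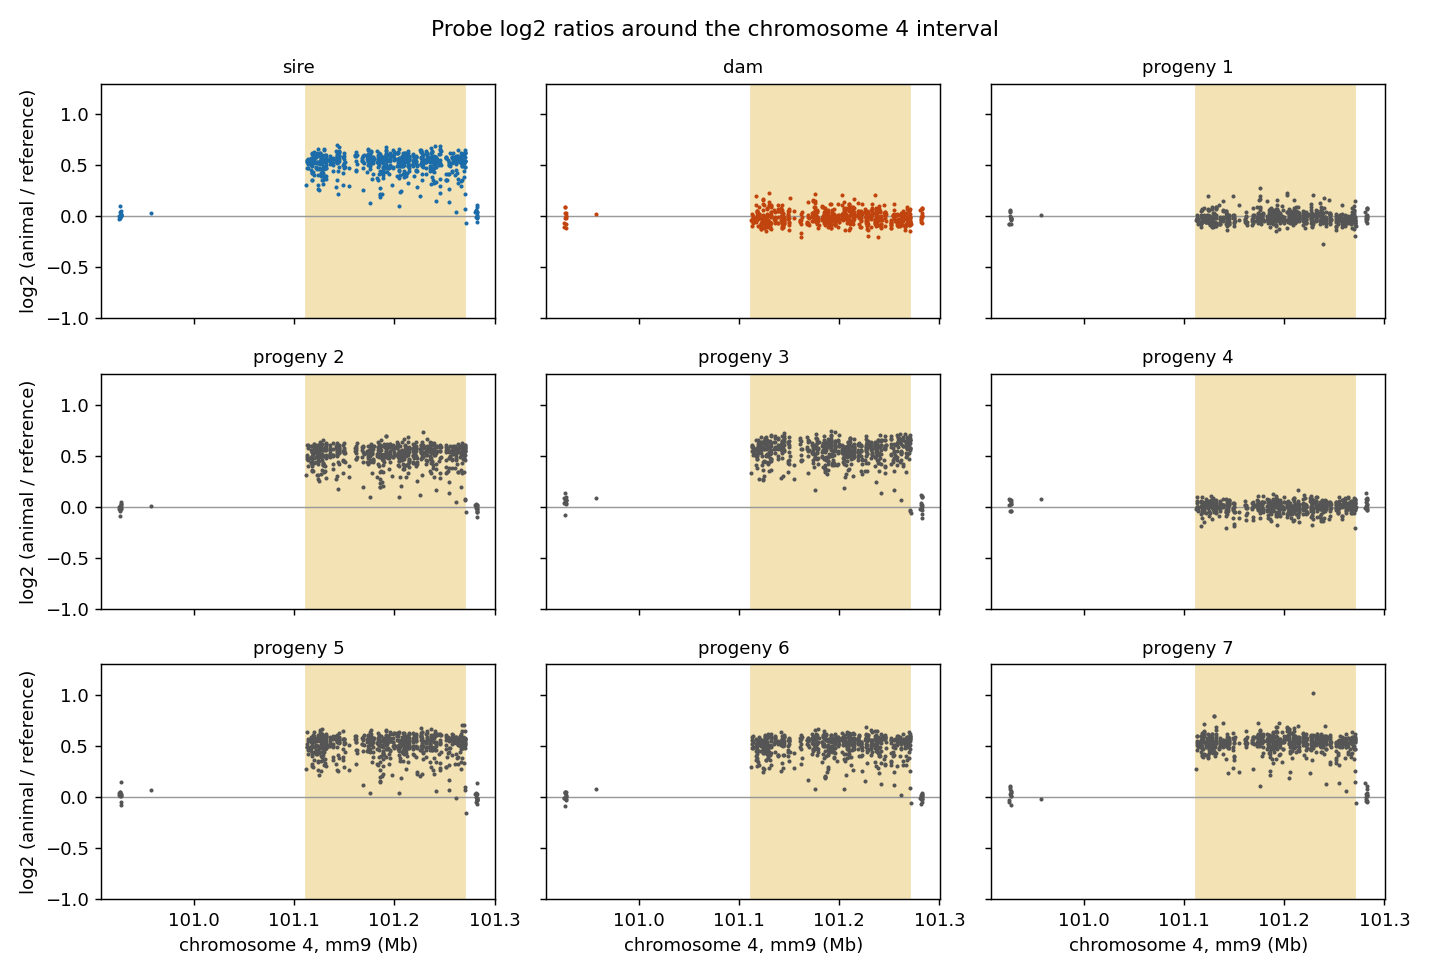
Log2 ratio (animal over reference, vertical axis) of each probe, averaged over both dye orientations, against its position on chromosome 4 of mm9 in Mb, 1 panel per animal, with the interval shaded. Probes in the interval center near 0.5 in the sire and in progeny 2, 3, 5, 6 and 7, and near 0 in the dam, progeny 1 and progeny 4.

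On chromosome 14 every animal had a lower ratio than the reference. The leading region, from 53712663 to 53759816 with 21 probes, had a mean log2 ratio of -0.83 in the sire, -0.84 in the dam and -0.85 ± 0.03 in the progeny (SD, n = 7). The 9 animals lay between -0.88 and -0.80. Further along, the region from 54122647 to 54178905 (11 probes) was at -0.59 in the sire, -0.61 in the dam and -0.50 ± 0.05 in the progeny, and the region from 54290601 to 54332250 (10 probes) at -0.46, -0.56 and -0.51 ± 0.04. These were the 3 regions called in all 9 animals. With normexp background correction only 1 region was called in all 9, and the means over the called animals of the regions from 54122647 and 54290601 moved from -0.52 to -0.39 and from -0.51 to -0.36. In each of the 3 the ratio alone does not say whether the animals or the reference mouse differ from the usual copy number. Between them, the regions from 53981793 to 53991948 (5 probes) and from 54223715 to 54278516 (8 probes) were each called lower in 7 animals. These last 4 regions were less even than the leading one, with a spread of 0.13 to 0.30 between the lowest and the highest animal against 0.08 there.

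Progeny were above the parents in 2 of these chromosome 14 regions before adjustment. The difference was 0.17 from 53981793 and 0.10 from 54122647, each with p = 0.0278 in the exact permutation test, which is the smallest p that 36 choices allow. Neither passed the adjustment over 279 regions (adjusted p = 0.914). Chance alone would bring about 1 in 36 regions to that smallest p, and 2 of 279 is a smaller share. Both parents were on slide 1 and no progeny was, so a slide difference cannot be told apart from these 2 differences. With normexp background correction, and without probes not well above background, 0 regions had an unadjusted p below 0.05.

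**Figure D3:**
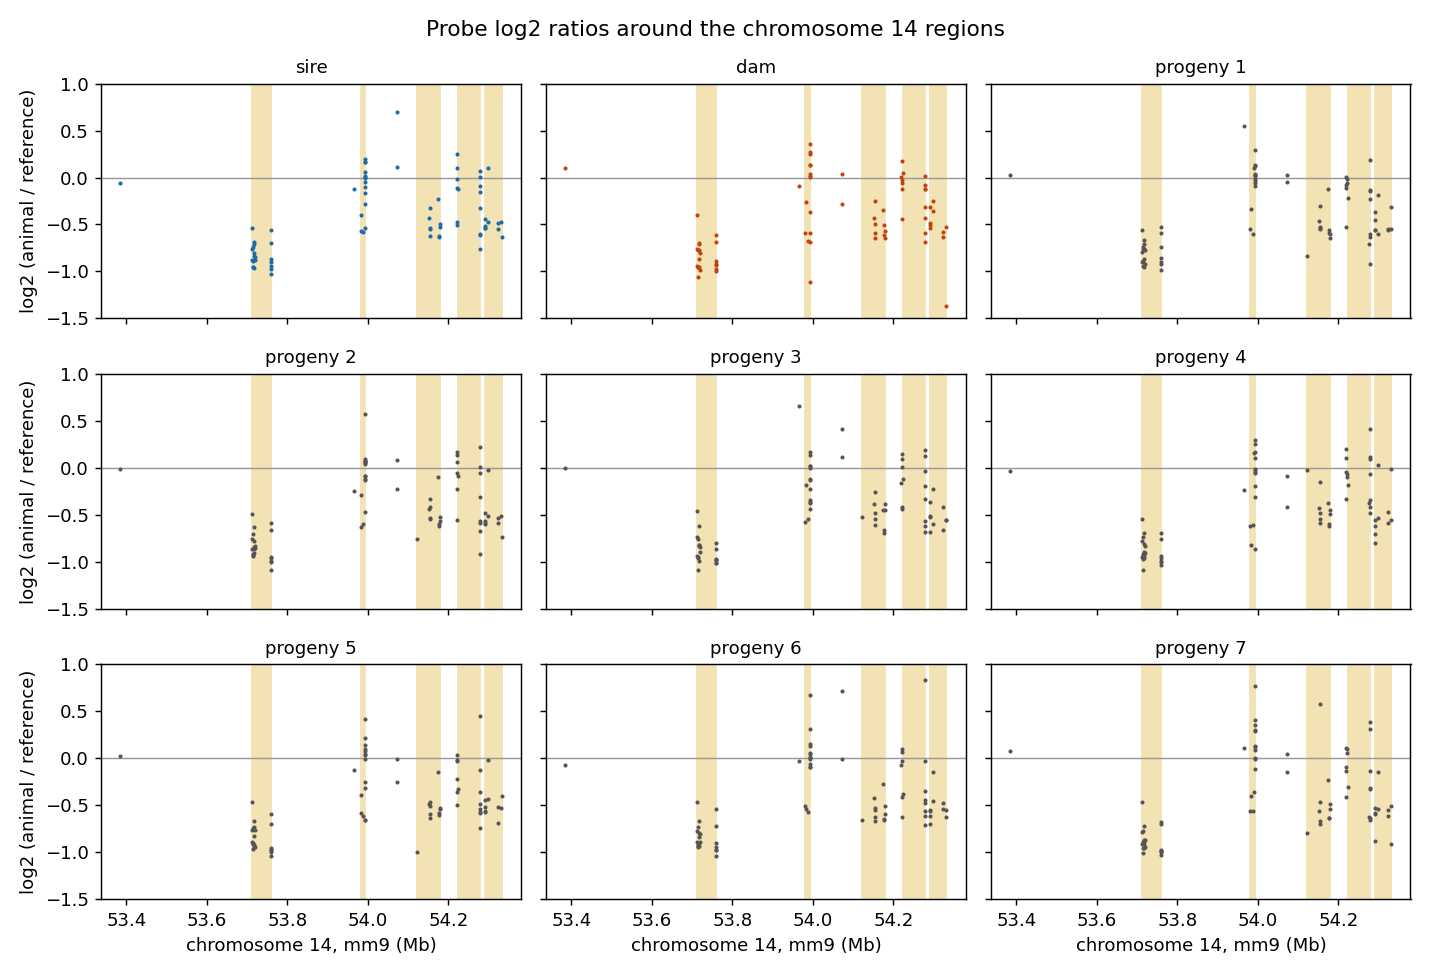
Log2 ratio (animal over reference, vertical axis) of each probe, averaged over both dye orientations, against its position on chromosome 14 of mm9 in Mb, 1 panel per animal, with the 5 called regions shaded. The leading region lies between -0.88 and -0.80 on average in all 9 animals, and the regions called in all 9 animals further right have progeny means of -0.50 and -0.51.

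Most other calls were short. Outside the chromosome 4 and chromosome 14 regions, 265 called autosomal regions held 5 to 14 probes each and were under 2 kb long, with a median of 604 bp, and they lay on all 19 autosomes. Higher ratios made up 264 of them. Over these 265 regions the median log2 ratio was 0.36 in the dam, 0.35 in progeny 1, 0.29 in progeny 7 and 0.27 in progeny 5. It was 0.15 in progeny 6, 0.12 in the sire, 0.07 in progeny 2, 0.05 in progeny 4 and -0.05 in progeny 3. In animals called at many of these regions the medians were alike with the animal in Cy5 and in Cy3, for example 0.34 and 0.37 in the dam and 0.28 and 0.32 in progeny 7. The calling rule asks for the same sign on each array, so this likeness was partly built in. In progeny 2, 3 and 4, called in 0 of the regions, the medians were 0.04 and 0.11, -0.004 and -0.084, and 0.05 and 0.04. Over the 19 autosomes taken singly, the median lay between 0.06 and 0.16 in the sire, 0.28 and 0.40 in the dam, and 0.30 and 0.41 in progeny 1. It lay between 0.05 and 0.10 in progeny 2, -0.08 and 0.02 in progeny 3, 0.02 and 0.07 in progeny 4, 0.24 and 0.31 in progeny 5, 0.12 and 0.17 in progeny 6, and 0.27 and 0.34 in progeny 7. The regions with the highest means over the called animals were at 7074180 on chromosome 18, 45162030 on chromosome 11 and 92612514 on chromosome 15, with means of 0.44, 0.43 and 0.42 over the same 4 animals each: the dam and progeny 1, 5 and 7.

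**Figure D4:**
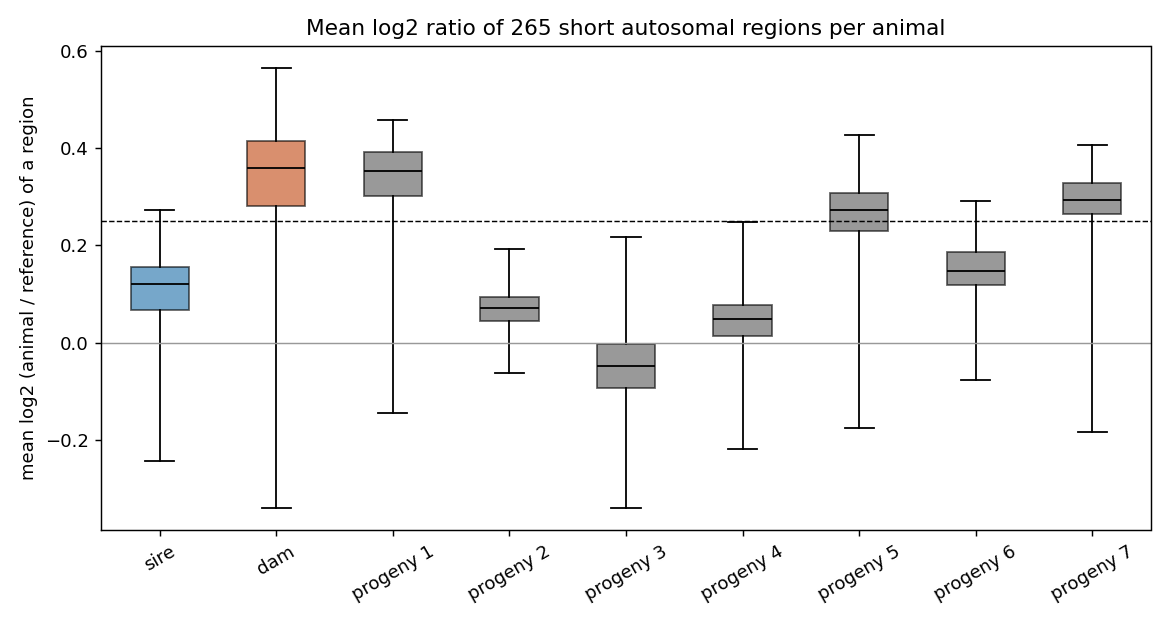
Mean log2 ratio (animal over reference, vertical axis) of 265 short autosomal regions in each animal (horizontal axis). Boxes span the quartiles with the median as a line, whiskers reach the lowest and highest region, and the dashed line is the calling minimum of 0.25; medians run from -0.05 in progeny 3 to 0.36 in the dam.

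The number of called segments was 13 in the sire, 221 in the dam, 241 in progeny 1, 25 in progeny 2, 13 in progeny 3, 2 in progeny 4, 175 in progeny 5, 22 in progeny 6 and 229 in progeny 7. Outside the chromosome 4 and chromosome 14 regions lay 2 of them in the sire, 218 in the dam, 239 in progeny 1, 0 in progeny 2, 3 and 4, 160 in progeny 5, 4 in progeny 6 and 216 in progeny 7. The chromosome 4 interval held 8 in the sire, 22 in progeny 2, 9 in progeny 3, 11 in progeny 5, 13 in progeny 6 and 10 in progeny 7. With the sign of 1 array left unturned, which cancels true differences and keeps noise and dye bias, 2 to 14 segments were called per animal. In the sire, progeny 3, progeny 4 and progeny 6 that background was 5, 7, 8 and 13 segments, so in progeny 4 the number of calls did not exceed it. Both calls of progeny 4 lay in chromosome 14 regions called in all 9 animals, so the number alone does not mark them as noise. Outside the chromosome 4 and chromosome 14 regions, the 2 calls in the sire and 4 in progeny 6 did not exceed the background either. That background keeps the dye bias that the average of the turned arrays cancels, so it cannot mark these calls as noise. With a minimum of 20 probes, chosen after seeing the data, 57 segments were left over the 9 animals in place of 941.

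The number of single probes past 0.5 in both orientations was made up differently. In the sire 180 probes were higher, 178 of them in the chromosome 4 interval, and 31 were lower, 29 of them in the chromosome 14 regions. Progeny 1 and progeny 4 had no such probe in the chromosome 4 interval, with 48 and 5 higher probes in all. In progeny 2, 3, 5, 6 and 7 the interval held 171 of 174, 245 of 249, 147 of 156, 122 of 131 and 172 of 235 higher probes. On X, 47 probes were higher in the dam and 47 in progeny 7. The background count with 1 sign unturned, which also keeps the dye bias, was 26 to 83 probes per animal. In progeny 4 it was 46 against 43 probes in all, so its probe count did not exceed it either, though 29 of the 43 lay in the chromosome 14 regions.

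The study asks which differences from the reference progeny share with a parent and which they show alone. The called segments merged into 279 regions. Of these, 232 were called in at least 1 parent and at least 1 progeny but not in all 9 animals, 41 in progeny only, 3 in parents only and 3 in all 9 animals. Among the 232, 223 were called in the dam and not in the sire, 5 in the sire and not in the dam, and 4 in both parents. The 5 that only the sire shared with progeny were the parts of the chromosome 4 interval. All 279 regions lay on autosomes: no segment was called on X, though 47 of its probes were higher in the dam and 47 in progeny 7. Breaks at gaps over 100 kb left 7889 stretches of probes, of which 6358 held at least 5 probes. In the other stretches no segment could be called.

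All 41 regions called in progeny only were short, with 5 to 12 probes, and were higher. They were called in progeny 1 (32 regions), progeny 7 (24) and progeny 5 (3), and in no other progeny. Their means over the called animals ran from 0.25 to 0.33. The dam lay just under the calling rule in many of them: its median was 0.18, and it was at 0.2 or more in 16 of the 41. On chromosome 4 from 139546126, a segment of 5 probes was called in the dam itself (0.275), but the dam was not called over the merged region of 6 probes. The largest of the 41 was on chromosome 3 from 51658688 to 51659014, with 0.36 in progeny 1, 0.31 in progeny 7 and 0.25 in the dam. On chromosome 2 from 111785495 to 111786095, progeny 1 was at 0.38 and progeny 7 at 0.26 while progeny 3 was at -0.34, the sire at -0.24 and the dam at 0.18. The other 6 of the 8 largest, on chromosomes 1, 8, 12, 17 and 19, had means of 0.29 to 0.33. In the one on chromosome 1 from 34413054 the dam was at 0.30, above progeny 7 at 0.27, which was called. The dam passed the minimum mean of 0.25 there but not the rule on each array. No progeny-only region had 20 or more probes. The 3 parents-only regions were all called in the dam alone: -0.34 on chromosome 17 from 57387089, 0.27 on chromosome 3 from 29978916 and 0.26 on chromosome 14 from 48549035. Progeny 1 and progeny 7 lay just under the rule in the chromosome 14 region, at 0.246 and 0.247. They were at 0.19 and 0.17 in the chromosome 3 region. On chromosome 17 the sire and progeny 1, 5 and 7 lay between -0.18 and -0.14.

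Across all 139043 probes measured in every animal, the progeny differed from the reference at 72 probes (limma, adjusted p below 0.05 and an absolute log2 ratio of at least 0.25), 46 lower and 26 higher. Of the 46 lower probes, 44 lay in the chromosome 14 regions, which hold 55 probes. Among those with the smallest adjusted p was probe A_67_P09562148 at 53714075 on chromosome 14, with a log2 ratio of -0.96 over 7 progeny (limma adjusted p = 5.06e-10). Of the 26 higher probes, 13 lay in the short regions and 1 in the chromosome 4 interval. The reference is 1 mouse, so its own spread is left out of this test. The number of higher probes was unstable: 454 probes were called with normexp background correction, 412 higher and 42 lower, and 547, 318 or 442 probes without progeny 1, 3 or 4.

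Between progeny and parents no probe passed in limma (0 of 139043, smallest adjusted p = 0.973), with 5420 probes at an unadjusted p below 0.05. These 5420 are a smaller share than the 0.05 that chance alone gives on average. With scan day as a block, chosen after seeing the data, the count was 0 with 3556 probes at an unadjusted p below 0.05, and within the first scan day, which held both parents and progeny 1 and 2, it was 0 with 2728. In the exact permutation test of the 279 regions 0 passed after adjustment and 2 had an unadjusted p below 0.05. That 0 was nearly fixed by the design: with 0.0278 as the smallest p that 36 choices allow, at least 156 of the 279 regions would need that p together for any to pass. Within the first scan day the smallest p that 6 choices allow is 0.333, so nothing could pass there. The limma test compares group means, so it can detect a shift shared by most progeny but hardly a change in 1 of them. In the chromosome 4 interval, called in the sire and 5 of the 7 progeny, 0 of 607 probes passed it.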

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

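Among the 7 progeny, 31 measures were screened for an animal far from the others, by whether its gap to the next animal, over the whole range, was above Dixon's 95% critical value. Chance alone marks about 1 in 20 groups. The 3 measures that met this all concern progeny 7. Tests of explanations in this part were chosen after the results were seen, except the one that uses loess.

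Progeny 7 had a median X log2 ratio of 0.95, with the other 6 between -0.01 and 0.01, and a median Y log2 ratio of -4.12 (SD over 3 probes 2.78), with the others between -0.06 and 0.05. The dam's values were 0.93 and -3.15, so both measures set progeny 7 apart as a female among males would be. The third measure was the median over 33 autosomal probes on 14 chromosomes that were low in the dam (at least 0.7 below 0) and not in the sire: -1.20 in progeny 7, -0.06 to 0.00 in the other progeny and -1.23 in the dam. Losses inherited from the dam are argued against: the probes lie on 14 chromosomes, and losses on different chromosomes would pass to progeny independently, though those close together would pass as a unit. Instead 97.0% of them were low in progeny 7 and 0% in the other 6, a spread of 97.0 percentage points. A candidate explanation is that these probes match sequence on the Y chromosome. The progeny medians fell on the same side of -0.35 as the Y probes in 7 of 7 progeny, but only progeny 7 lay below it, so this agreement rests on 1 animal. Probe sequences were not compared with the Y chromosome here, so the match stays a hypothesis.

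The short higher regions form a second pattern, in which the dam and progeny 1, 5 and 7 pass the calling rule at many places at once. A trend of the ratio with spot intensity is argued against as the whole cause, because after loess the dam's median over the short regions was still 0.35. Slide and scan day are argued against because the dam exceeded the sire, on the same slide and day, by 0.24 over 260 short regions found from progeny segments alone. Gains inherited from the dam are argued against as well: of 221 short regions called in the dam and not in the sire, on 19 chromosomes, 98.2% were called in progeny 1, 0% in progeny 2, 3 and 4, 71.9% in progeny 5, 0.905% in progeny 6 and 88.2% in progeny 7. That is a spread of 98.2 percentage points. Regions close together on a chromosome would pass as a unit, but those on different chromosomes would pass independently. A difference between animals in DNA preparation, or in how their ratios follow local base composition, may remain as a cause and was not tested. The same holds for any biological difference that affects many places alike.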

How the results depend on the processing

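The minimum of 20 probes, joining regions under 1 kb apart and both scan day settings were chosen after seeing the data. The chromosome 4 interval kept 6 called animals and the leading chromosome 14 region kept 9 under each of the 9 alternatives run for them, and the sire's chromosome 4 mean stayed between 0.52 and 0.53 over 5. Progeny against parents gave 0 probes in all 18 alternatives, slide as a random block and leaving out each animal included. It also gave 0 regions in all 14, which says little of stability: with 36 choices at least 156 of 279 regions would need the smallest possible p together. Without the sire or the dam, the lone parent is assumed to vary like the progeny. The dam's X median was 0.97 with normexp and moved by less than its spread otherwise. No called value reversed.

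Probes past the threshold totalled 1721 at 0.5, 7913 at 0.3 and 47 at 1. Called segments (941) and regions (279) became 252 and 117 at a minimum mean of 0.4, 1693 and 527 with 3 probes, 149 and 37 with 10, and 57 and 6 with 20. Regions called in parent and progeny (232) numbered 56 at a minimum mean of 0.4, 408 with 3 probes, 28 with 10 and 5 with 20. Regions called in progeny only (41) numbered 13 at 0.4, 95 with 3 probes, 6 with 10, 0 with 20, 27 at a penalty of 6 and 92 with the Cy5 orientation alone. Regions called in parents only (3) numbered 7 at a minimum mean of 0.2, 45 at 0.4, 19 with 3 probes, 0 with 10 or 20, 6 at a penalty of 6, and 15 and 13 with the Cy5 or Cy3 orientation alone. Regions called in all 9 animals (3) numbered 1 with normexp or 20 probes and 6 with 50% reciprocal overlap. Most regions hold few probes at means near the calling minimum. Whether this accounts for the changes in the counts was not tested.

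Progeny against reference (72 probes) gave 163 with no minimum fold and 454 with normexp, and 57 to 547 with a progeny animal left out: 547, 318 and 442 without progeny 1, 3 and 4. The cause was not tested. Among further values for single animals and regions, 78 of 472 moved beyond their spread or 1.5 times. The GC trend and gene list alternatives were not run. At least 99.8% of spots were well above background. Leaving out probes that were not took the regions at an unadjusted p below 0.05 from 2 to 0. Probes past the threshold in progeny 4 (43, against a background of 46) numbered 25 with normexp and 32 without dim probes. No paired analysis was possible because the labels pair no parent with a progeny: replicate numbers count different animals. Slide and scan day are the shared units, and the fits above use them as blocks. Both parents were on slide 1, which held no progeny, so the slide block cannot separate slide from the difference between progeny and parents.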

Other observations

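The tests on the chromosome 4 interval were chosen after its values were seen. Slide and scan day are argued against, since animals on the same slide differed by up to 0.55 (progeny 3 and progeny 4). The profile behind the short regions is argued against too, since the dam, which was highest over those regions, was at -0.0085 over the interval. A hypothesis is that the sire carries 1 extra copy and passed it to some of its progeny: its mean of 0.52 lies below the 0.58 of 3 copies over 2, as the X probes of the dam lie below 1 at 0.93. The 5 called progeny of 7 (71.4%, exact Clopper-Pearson 95% interval 29.0% to 96.3%, counting error only) are consistent with transmission at 50 percent (exact binomial test, two-sided, p = 0.453). With 7 progeny this interval excludes little, and whether the copy was new in the sire or older in the colony was not tested.

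Probes with the lowest ratios in the dam among the 33 were at 132549431 on chromosome 3 (-2.66 in the dam, -2.62 in progeny 7), 104241394 on chromosome 6 (-2.35 and -2.23) and 47119221 on chromosome 8 (-2.15 and -2.12), while the sire was at 0.12, 0.09 and 0.11. There were 3 probes among the 33 between 25421508 and 25432685 on chromosome 3. A set of 11 autosomal probes chosen the other way, high in the dam and not in the sire, had medians of 0.13 in the sire, 0.81 in the dam, 0.48 in progeny 1, 0.02 in progeny 2, -0.09 in progeny 3, 0.00 in progeny 4, 0.44 in progeny 5, 0.20 in progeny 6 and 0.32 in progeny 7. Of these 11 probes, 3 lay in the short regions. The probes of the short regions had a lower mean log2 intensity than other autosomal probes (9.51 against 9.97), and 66.7% of them against 62.6% had the full length of 60 bp.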
